A study of Mus musculus with 2 samples.

How the data were processed

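Single-cell RNA sequencing libraries were made with the GEXSCOPE microwell kit from CD45.2-positive, CD3-negative, NKp46-positive cells sorted from dissociated tumours, per the labels' protocols. Cells of 1 treatment group were pooled, and the libraries were sequenced as 150 bp paired-end reads to a planned mean of 50000 reads per cell, per the labels. The deposited values are UMI counts per gene and cell barcode, not normalized, and each library had been reduced to called barcodes before deposit. Cutadapt, featureCounts, Seurat version 4, Scanpy and the build mm10 are named in the submitters' processing notes, without their roles. The aligner, the gene annotation and the method of calling cells are not given in the sources used here. Groups were taken from the sample titles. The series title names IL-21 and its combination with IL-15 in place of the groups the sample titles name, and the sample titles were followed.

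The files list 53715 genes, of which 53620 IDs are in GENCODE M21. A total of 118 symbols were shared by more than 1 ID and were resolved by ID. Il2rg, a gene on which NK cells depend, had 0 UMIs, and several mitochondrial genes such as mt-Co2 and mt-Co3 had almost none while mt-Co1 and mt-Cytb were abundant. A value of 0 in these files can thus reflect how reads were assigned to genes, and the mitochondrial share of UMIs is understated: 7 of 13 mitochondrially encoded genes were measured.

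Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept, which removed 0 barcodes of the IL-15SA library and 5 of the combination library. The automatic threshold of Scrublet marked 5 and 3 cells (0.0596% and 0.0241%), which is too few to have worked, so the 5% of cells with the highest doublet score were removed, 419 and 622 cells, leaving 7967 and 11808. Cells were scaled to 10000 UMIs and clustered on 2000 variable genes, 30 principal components and 15 nearest neighbours with the Leiden method at resolution 0.5, without integration of the libraries, which gave 10 clusters. Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, leidenalg 0.10.2 and igraph 0.11.9 were used.

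A cluster was named for a class other than NK cells when at least 3 of that class's markers were at 5 times their median over clusters and the median ratio of NK markers was under 0.67. The markers, the gene lists and the rule for named genes were fixed before the data were examined, and these naming thresholds were set afterwards. Clusters 5 and 8 were thus tumour or stroma-like. Cluster 8 was led by Saa3, Dcn and Cxcl5, and cluster 5 held few UMIs and mixed tumour and NK transcripts. The other 8 clusters formed the NK compartment. Clusters 1, 3 and 7 held markers of other classes among their top 10 genes, such as Cd3g and Cd3d in cluster 1, Cd74 and H2-Aa in cluster 3 and Mcpt8 in cluster 7, so clusters are given by number. Cluster 3 also held the innate lymphoid cell type 1 (ILC1) markers Il7r and Cxcr6 among its top 10 genes. ILC1 carry NKp46 and pass the sort, so the NK compartment can include them. Cluster 2 was led by Esco2, Rrm2 and histone genes, cluster 4 by Cma1, S1pr5 and Ccl5, cluster 6 by Slfn5, Ifit2 and Mx2, cluster 7 by Gzmg, Gzmd and Gzmf, cluster 9 by Ccnb2 and Cenpa, and cluster 10 by Gm29328. Sizes of the clusters within the NK compartment were not compared between libraries, since genes that lead several of them, such as Cd74, Ccl5, Ifit2 and Gzmd, differed between the libraries. The share of clusters 5 and 8 is given per library.

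UMI counts were summed over the NK compartment of each library, 27386344 and 29133491 UMIs, and divided by the total to give CPM. Ratios are the combination library over the IL-15SA library unless a sentence says otherwise. Intervals of CPM are exact Poisson intervals, those of ratios are exact conditional binomial intervals and those of shares are exact binomial (Clopper-Pearson) intervals, all at 95% and covering counting error only. For log2 ratios, and so for each count of genes past 1.5-fold or 2-fold, 1 CPM was added to both values. Ratios printed with an interval have nothing added. Genes at 20 CPM or more in 1 library entered the counts of genes past 2-fold. With 1 library per group no test was made and no p-value is given. For the 22 gene lists, members at 5 CPM or more in 1 library were used, and the median log2 ratio was placed among 10000 random lists matched in 20 bins of expression, as a description of these libraries. For shares of cells with a UMI each cell was thinned to 1000 UMIs.

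The genes named were set by a rule: the 12 highest and 12 lowest log2 ratios at 20 CPM or more, leaving out mitochondrial, ribosomal protein, haemoglobin and model genes and genes over 5 times higher in the non-NK clusters, then the 4 members of each list with the largest log2 ratio in size, then a fixed set of key genes. The text gives values for part of the genes that the rule names, and 1 result is not reported here. The genes Lrp1, Cd63, Pcolce and Rhox5 are named outside this rule and were chosen after their values were seen, as were Gzmc as part of the granzyme sum and genes that name a cluster or an unmeasured gene.

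The ratio and interval steps were tested on simulated data: with 200 of 5250 genes altered 3-fold in counts drawn for this comparison, 200 were found past 2-fold, as were 0 of the 5050 others, and 95.3% of intervals of unaltered genes held the true ratio. This checks the arithmetic for counting error only. It says nothing of variation between libraries or mouse pools, which 1 library per group leaves unmeasured. Alternatives were TMM factors from edgeR 4.0.16, median of ratios size factors from DESeq2 1.42.0 (R 4.3.3), no filter on low values and a filter at 50 CPM, 5 CPM added, all retained cells, removal of cycling clusters, an Ncr1 gate, doublets kept, a filter of 500 genes and 10% mitochondrial UMIs, equal weight per cell, other thinning depths and resolution 1.0. Alternatives chosen after seeing the data were cells matched on UMIs, removal of cluster 3, a resolution 1.0 compartment without 5 clusters, cluster 8 alone, and removal of clusters 2 and 9. The last was added because the rule fixed for cycling clusters, at least 3 cell cycle list genes among the top 10, took cluster 9 alone and missed cluster 2. For the matching, cells of both libraries were drawn in equal number, 6578 each, within 8 bins per doubling of UMIs.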

Results

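Natural killer (NK) cells were sorted from CT26 colon carcinoma tumours that by the labels lack B2m, the invariant chain of MHC class I, and were profiled by single-cell RNA sequencing in microwells. By the sample titles, 1 library came from tumours treated with IL-15SA and 1 from tumours treated with IL-15SA plus IL-21Fc. The cells of each treatment were pooled before loading, so each group had 1 library and the differences below have no replicate check. The IL-15SA library held 8386 barcodes with 30893388 UMIs and a median of 1290 genes per cell, and the combination library held 12435 barcodes with 35336180 UMIs and a median of 1071 genes. After removal of doublets and of clusters with tumour or stroma markers, the NK compartment held 7404 and 10445 cells, with a median of 3114 and 2370 UMIs per cell. Levels are CPM, each gene's share of the UMIs summed over these cells on a scale of 1000000, and the 95% intervals cover counting error only.

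The comparison asks how tumour-infiltrating NK cells differed when IL-21Fc was given together with IL-15SA. In the combination library the NK compartment had higher levels of chemokine genes, genes of the type I interferon response list and the surface receptor gene Cd7. Levels of most granzyme genes, Havcr2, Tnfrsf9 and genes of growth metabolism were lower. Ccl5, a chemokine that attracts T cells, was at 3370 CPM in the IL-15SA library and 8147 CPM in the combination library, a ratio of 2.42 (95% interval 2.40 to 2.44). Gzmd, a granzyme of the granule exocytosis pathway, was at 225 and 94.4 CPM, which was 2.39-fold lower in the combination library (2.28 to 2.50). Havcr2, which encodes the inhibitory receptor TIM-3, was at 25.5 and 9.51 CPM, which was 2.68-fold lower (2.33 to 3.09). Ccl5 is among the leading genes of cluster 4, and Gzmd and Havcr2 are among those of cluster 7. The values of all 3 genes thus also depend on how cells spread over clusters. The log2 ratio of Ccl5 was 1.27 over the compartment and, within clusters, ran from 0.66 in cluster 6 to 1.41 in cluster 2. Within clusters the log2 ratio of Gzmd ran from -2.04 in cluster 2 to 0.01 in cluster 7. That of Havcr2 ran from -1.72 in cluster 3 to -0.43 in cluster 4.

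Of 5421 genes at 20 CPM or more in at least 1 library, 12 were at least 2-fold higher and 10 at least 2-fold lower in the combination library. Counts of genes past a fold use ratios with 1 CPM added to both values, whereas the ratios printed for single genes have nothing added, so a gene such as Rtp4, at a printed ratio of 2.02, is not among the 12. Of the 12 higher genes, 4 (Lrp1, Cd63, Pcolce and Rhox5) were over 5 times higher in the tumour or stroma-like cells than in the NK compartment. Among the other extremes, Cd74, H2-Aa and H2-Eb1, which serve MHC class II antigen presentation, had ratios of 3.81 (3.47 to 4.19), 2.87 (2.52 to 3.27) and 2.66 (2.32 to 3.06). These 3 genes lead cluster 3, and without that cluster their log2 ratios were 0.99, 0.78 and 0.91, against 1.88, 1.44 and 1.33 with it. With a finer clustering and 5 clusters left out they were 1.02, 0.71 and 0.93. The protease gene Cma1 was at 16.1 and 43.0 CPM, with a log2 ratio of 1.37. It leads cluster 4, and within clusters its log2 ratio ran from -0.81 in cluster 9, 0.13 in cluster 3, 0.23 in cluster 1 and 0.89 in cluster 4 to 1.37 in cluster 6, 1.70 in cluster 2 and 2.85 in cluster 7. No interval is given for these within-cluster ratios, and clusters 7 and 9 held 254 and 269 cells of the combination library. Values of the whole compartment also depend on how the cells of each library spread over the clusters. The chemokine receptor gene Cxcr4 was at 12.3 and 27.8 CPM. Cd7 was at 452 and 911 CPM, a ratio of 2.02 (1.97 to 2.06). On the lower side, Ifitm1, an interferon-induced membrane protein gene, was at 859 and 347 CPM, which was 2.47-fold lower in the combination library (2.42 to 2.53). It is also among the leading genes of cluster 7, and its log2 ratio ran from -1.66 in cluster 3 to -0.09 in cluster 7. Ltb4r1, the leukotriene B4 receptor gene, was 2.29-fold lower (2.01 to 2.61), and the transcriptional repressor gene Zbtb32 was 1.82-fold lower (1.72 to 1.92). When cells of both libraries were matched on UMIs per cell, 4 genes were at least 2-fold higher and 3 at least 2-fold lower. Ifit3, at a matched log2 ratio of 1.14, left this count by the filter at 20 CPM and not by its ratio. After that matching the log2 ratio was 0.85 for Ccl5, -0.92 for Gzmd, -0.92 for Havcr2, 0.75 for Cd7 and -0.95 for Ifitm1.

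**Figure D1:**
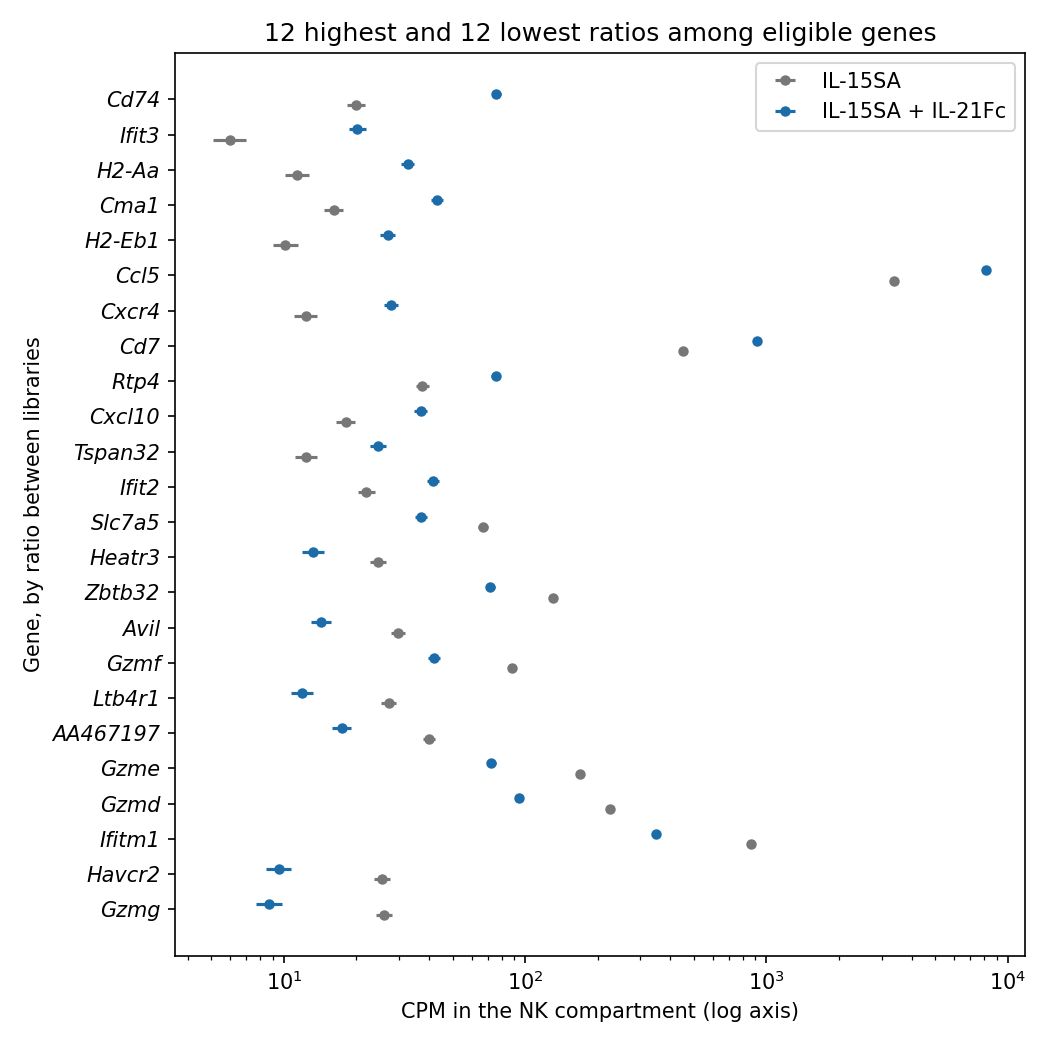
Levels of the 12 genes with the highest and the 12 with the lowest ratio between libraries after leaving out model genes and genes over 5 times higher in tumour or stroma-like cells, in CPM on a log axis; points are the 2 libraries and bars are 95% Poisson intervals that cover counting error only. Ccl5 lies at 3370 and 8147 CPM and Ifitm1 at 859 and 347 CPM.

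The cytotoxic effector list had a median log2 ratio of -0.10, at percentile 2.11 of 10000 random lists matched on expression. Of its 23 measured members, 14 were below 0 and 9 above 0, with 6 at least 1.5-fold lower and 0 at least 1.5-fold higher in the combination library. The 6 members at least 1.5-fold lower lay in the granzyme family, and Gzmg had the lowest log2 ratio in the list, at -1.47. After matching on UMIs per cell the list median was -0.11, with Gzmg at -0.85 and Gzmd at -0.92. Gzmb, which encodes granzyme B, was at 7269 and 5620 CPM, and Prf1, which encodes perforin, at 1910 and 1436 CPM, so that Prf1 was 1.33-fold lower (1.31 to 1.35). Gzma was at 17859 and 15646 CPM. Gzmb, Gzma and Prf1 were lower in the combination library in each of the 7 clusters with at least 100 cells per library. The granzyme genes Gzmc to Gzmg are near-identical neighbours, and reads shared among them leave each single value uncertain. Their summed level was 1540 CPM in the IL-15SA library and 843 CPM in the combination library.

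The cytokine and chemokine list had a median log2 ratio of 0.51, at percentile 100, with 8 of 16 measured members at least 1.5-fold higher and 0 at least 1.5-fold lower. After matching on UMIs per cell this median was 0.36. Within the 7 clusters it ran from 0.03 in cluster 6 to 0.37 in cluster 2, each below the 0.51 of the whole compartment. Xcl1, which attracts cross-presenting dendritic cells, was at 838 and 1330 CPM, a ratio of 1.59 (1.56 to 1.61). Ccl3 was at 219 and 374 CPM, and Ltb, which encodes lymphotoxin beta, at 509 and 843 CPM. Ccl5, Xcl1 and Ltb were higher in the combination library in each of the 7 clusters. Ccl3 was higher in all of them but cluster 6, where its log2 ratio was -0.018. Ifng, which encodes interferon gamma, was at 273 and 305 CPM, a ratio of 1.12 (1.09 to 1.16), and was higher in 3 of these clusters and lower in 4.

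The type I interferon response list had a median log2 ratio of 0.42, at percentile 100, and each of its 25 measured members was higher in the combination library, 9 of them by at least 1.5-fold. After matching on UMIs per cell this median was 0.28. Ifit3, an interferon-induced antiviral gene, was at 5.99 and 20.2 CPM, a ratio of 3.37 (2.83 to 4.03). Rtp4 was at 37.4 and 75.7 CPM and Ifi27l2a at 120 and 221 CPM. The median of this list was above 0 in each of the 7 clusters. Ifitm1, an interferon-induced gene outside this list, was lower in the combination library in each of these 7 clusters. Cells with tumour or stroma markers, in which Ifi27l2a was at 683 CPM, made up 7.07% of retained cells (exact binomial interval 6.51 to 7.65) in the IL-15SA library and 11.5% (11.0 to 12.1) in the combination library. Cluster 8 alone, the cluster with the fewest NK transcripts, made up 1.79% and 3.92%.

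Genes of growth metabolism were lower in the combination library. The list of MYC and ribosome biogenesis genes had a median log2 ratio of -0.32, with 24 of 25 measured members below 0, and the nucleolar gene Npm1 was at 2473 and 1774 CPM. The glycolysis list had a median of -0.29, with 19 of 20 members below 0, and Ldha, which encodes lactate dehydrogenase A, was 1.38-fold lower (1.35 to 1.40). The list of amino acid transport and one-carbon metabolism had a median of -0.33, with 15 of 17 members below 0, and the amino acid transporter gene Slc7a5 was at 66.9 and 37.0 CPM. All 3 medians lay at percentile 0 of their random lists. After matching on UMIs per cell they were -0.19, -0.21 and -0.10. The nuclear genes of oxidative phosphorylation had a median of -0.05 at percentile 26.8, and the TCA cycle list a median of -0.09 at percentile 5.42. After matching on UMIs per cell they were 0.03 and -0.04.

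S phase genes had a median log2 ratio of -0.23 and G2 and M phase genes of -0.15, both at percentile 0. Mki67, a marker of cycling cells, was at 170 and 141 CPM. S phase medians differed between clusters, from -0.67 in cluster 7 and -0.47 in cluster 1 to -0.0099 in cluster 2 and 0.06 in cluster 4. G2 and M phase medians were above 0 in 4 of 7 clusters, and ran from -0.43 in cluster 7 to 0.15 in cluster 9 and 0.16 in cluster 3. Both lists had medians above 0, of 0.05 and 0.19, when cells were matched on UMIs per cell. Cells of cluster 2, which is led by cell cycle genes, had 1.59 and 1.71 times the median UMIs of their library, so this matching also selects on the cell cycle and does not show which difference belongs to UMIs.

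The list of IL-21 and STAT3 response genes had a median log2 ratio of 0.21 at percentile 100, with 14 of 19 measured members above 0 and 0 at least 1.5-fold higher with 1 CPM added. Maf, a transcription factor gene, was at 27.1 and 41.0 CPM, Junb, which is also in the list of immediate early genes, at 1073 and 1593 CPM and Socs3, a feedback inhibitor of cytokine signalling, at 80.2 and 88.1 CPM. The log2 ratio of Maf was 0.58, and 0.23 after matching on UMIs per cell. Socs3 was higher in 3 of the 7 clusters and lower in 4. Of the 5 members below 0, Gzmb was lowest, at a log2 ratio of -0.37. The list median was 0.04 after matching on UMIs per cell. It was above 0 in 5 of the 7 clusters and below 0 in clusters 6 and 7. The list of IL-15 and STAT5 response genes had a median of -0.02 at percentile 44.3, and of -0.14 after matching. Its median was below 0 in each of the 7 clusters, from -0.06 in cluster 2 to -0.24 in cluster 3. Each of these lay further from 0 than the -0.02 of the whole compartment. Within this list, Cish, a feedback inhibitor induced by STAT5, was at 24.2 and 16.7 CPM. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, was at 572 and 354 CPM and lower in each of the 7 clusters. The receptor gene Il21r was at 16.8 and 21.5 CPM, Il2rb at 875 and 801 CPM, Il15ra at 11.7 CPM in both libraries and Stat3 at 170 and 191 CPM. Il21 and Il2rg had 0 UMIs in both libraries, which can reflect how reads were assigned to genes and sets no limit on their levels.

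The list of inhibitory and exhaustion-associated genes had a median log2 ratio of 0.10 at percentile 99.0, and its members went both ways. After matching on UMIs per cell its median was 0.02. Tox, a transcription factor gene, was at 11.0 and 20.7 CPM and Nr4a1, which is also in the list of immediate early genes that tissue dissociation can induce, at 370 and 565 CPM, while Entpd1, which encodes the ectonucleotidase CD39, was at 96.6 and 71.6 CPM. Activating receptors and adaptors had a median of 0.18 at percentile 100, and of 0.04 after matching, with Cd160 at 92.7 and 146 CPM and Klrk1, which encodes NKG2D, at 398 and 489 CPM. The 4 measured Ly49 receptor genes had a median of 0.0097 at percentile 70.0.

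**Figure D2:**
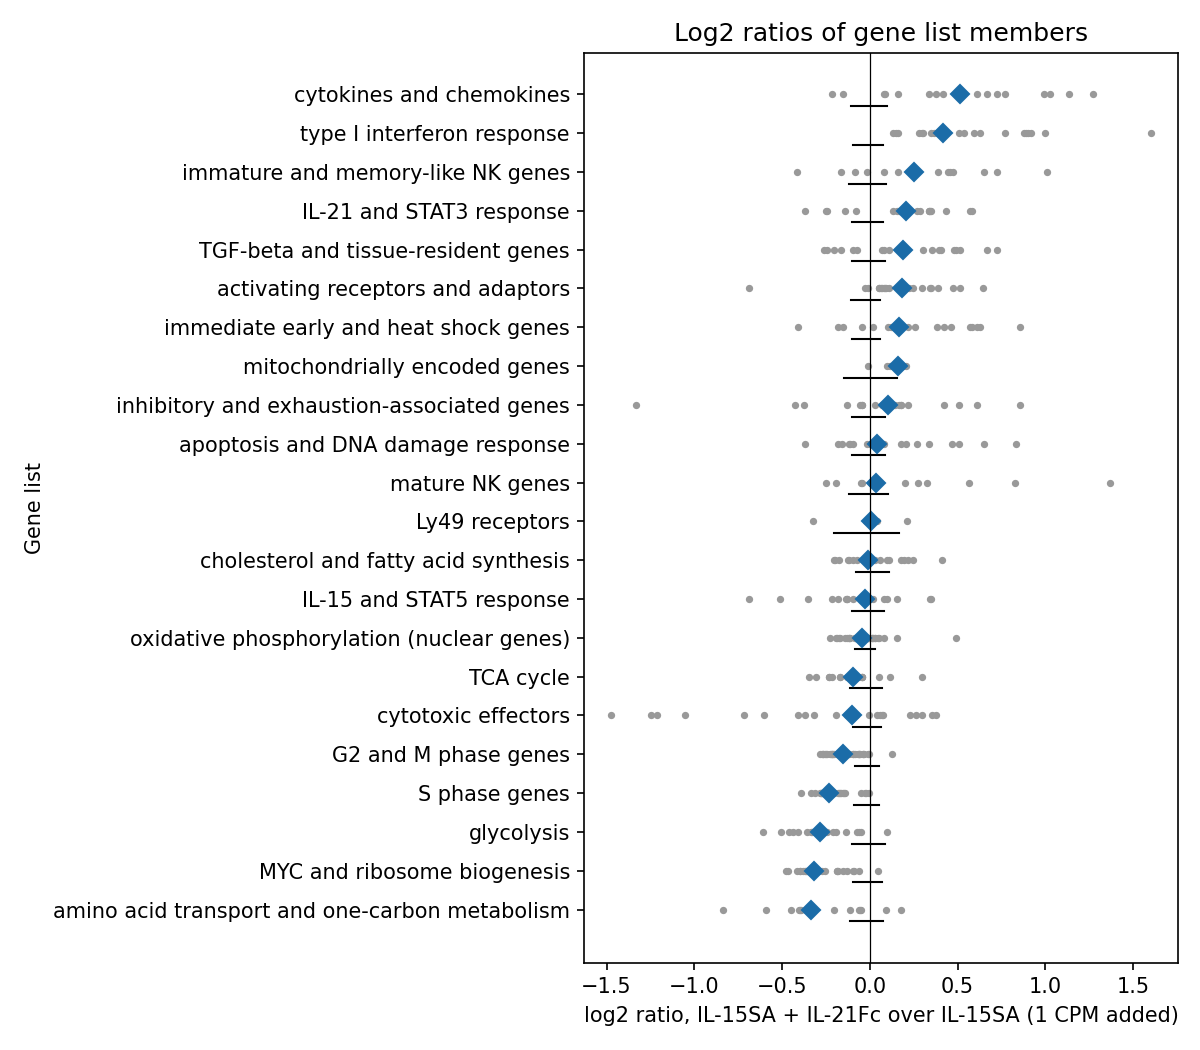
Log2 ratio of each measured member (grey points) and the list median (blue diamonds) for 22 gene lists, on a log2 axis; black lines span the central 95% of medians of 10000 random lists matched on expression. Medians run from -0.33 for amino acid transport and one-carbon metabolism to 0.51 for cytokines and chemokines.

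With each cell thinned to 1000 UMIs, which left out 0 cells, a Prf1 UMI was found in 74.2% of cells (73.2 to 75.2, exact binomial) in the IL-15SA library and 65.9% (65.0 to 66.8) in the combination library. Without thinning the shares were 91.7% and 83.9%. In cluster 8, whose stroma-like cells should lack Prf1, the thinned shares were 16.8% and 13.0%, at median depths of 5232 and 4751 UMIs before thinning. A Klrk1 UMI was found in 32.9% (31.9 to 34.0) and 38.4% (37.5 to 39.3) of thinned cells, against 4.90% and 5.83% in cluster 8 and 66.9% and 65.8% without thinning. Havcr2 UMIs were found in 1.92% (1.62 to 2.26) and 0.641% (0.497 to 0.814), against 0.699% and 0.216% in cluster 8 and 6.67% and 2.17% without thinning. Cluster 8 held 143 and 463 cells, so its Havcr2 shares rest on very few cells and do not show a difference in background. Pdcd1 UMIs were found in 0.527% and 0.574% of thinned cells, with intervals of 0.375 to 0.719 and 0.439 to 0.739, so no difference in the share was detectable at this depth. Over the summed UMIs Pdcd1 was at 6.90 and 9.61 CPM, a ratio of 1.39 (1.15 to 1.68). The thinned share with a Socs3 UMI was 7.33% and 8.05%, and 15.4% and 21.2% in cluster 8. The tumour or stroma-like cells had Socs3 at 182 CPM, so their share gives no background level for this gene.

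**Figure D3:**
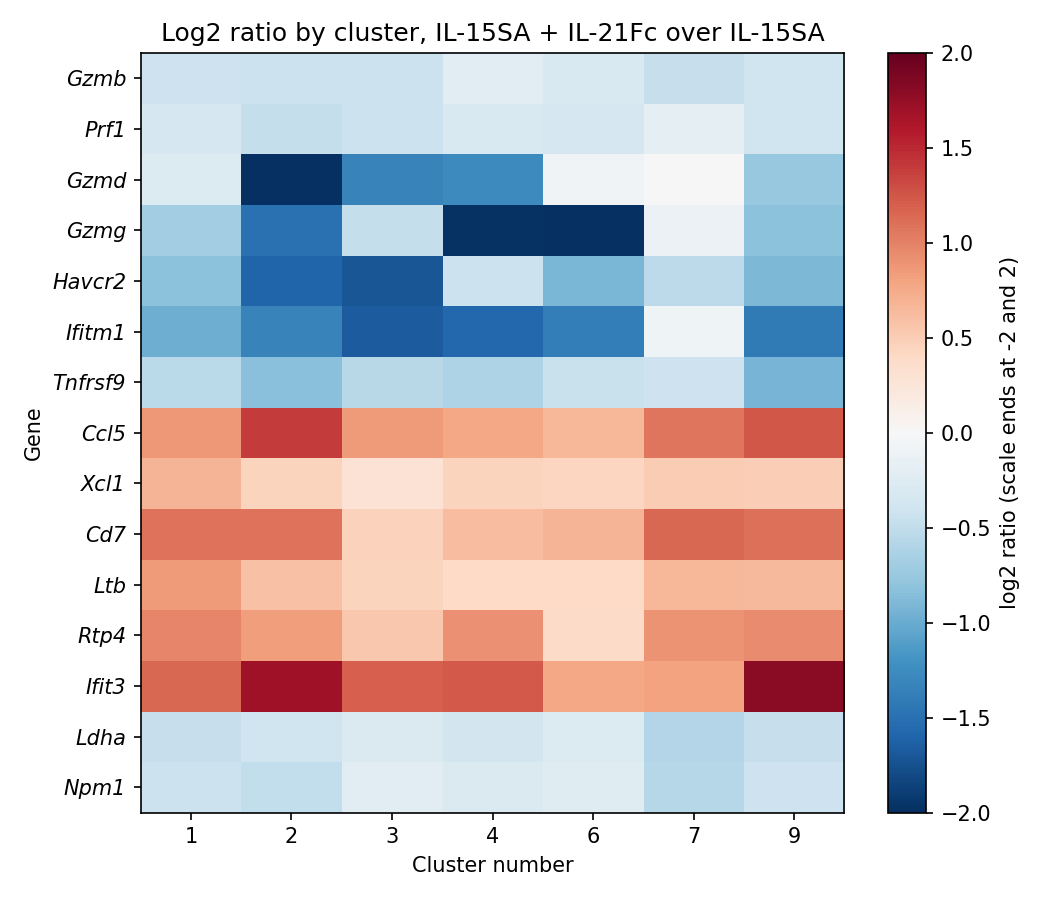
Log2 ratio between libraries (colour, scale ends at -2 and 2) of 15 genes within the 7 clusters of at least 100 cells per library. Ccl5 was higher and Gzmb lower in the combination library in all 7 clusters, whereas Gzmd differed by 0.01 (log2) in cluster 7.

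In the mm10 assembly, with positions from GENCODE M21, Ccl5 (ENSMUSG00000035042) lies on chromosome 11 from 83525778 to 83530518, and Havcr2 (ENSMUSG00000020399) on chromosome 11 from 46454935 to 46481255. Gzmd (ENSMUSG00000059256) lies on chromosome 14 from 56129556 to 56132608 and Gzmb (ENSMUSG00000015437) on chromosome 14 from 56258838 to 56262260. Ifitm1 (ENSMUSG00000025491) lies on chromosome 7 from 140967221 to 140969825. All 5 are protein-coding genes, and UMIs were counted per gene and not per exon or transcript.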

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

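The sort kept CD45.2-positive, NKp46-positive cells, and cells with tumour or stroma markers lie outside the comparison of NK cells. They made up 7.07% of retained cells (exact binomial interval 6.51 to 7.65) in the IL-15SA library and 11.5% (11.0 to 12.1) in the combination library. They drew attention because the sort should leave out such cells, and a signal above 0 is by itself no test of what they are. Most of them, 420 and 900 cells, lay in cluster 5, and cluster 8 alone made up 1.79% and 3.92%. In cluster 8, the stroma gene Col1a2 was at 930 and 860 CPM, against 14.6 and 28.5 CPM in the NK compartment, and a Ptprc (CD45) UMI was found in 69.9% and 69.3% of cells, against 99.4% and 99.5% in the NK compartment. Shares with a Ptprc UMI are not thinned here, and cells of cluster 8 had more UMIs, a median of 5232 and 4751. By level, Ptprc was at 315 and 331 CPM in cluster 8, against 3074 and 3340 CPM in the NK compartment. Cluster 5 mixed both kinds of transcript: it had Ncr1 at 965 and 733 CPM, against 1473 and 1571 CPM in the NK compartment, and a Ptprc UMI in 86.4% and 75.4% of cells. B2m, disrupted in the tumour cells by the labels, was at 4740 and 4479 CPM in cluster 8, against 4559 and 5097 CPM in the NK compartment. A disrupted gene can still give a transcript, so this does not show whether they are tumour cells. No explanation was tested for these cells.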

How the results depend on the processing

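No paired analysis was possible because each group had 1 library and the labels give no replicate numbers. Matching on UMIs per cell, resolution 1.0 without 5 clusters, cluster 8 alone and the removals of cluster 3 and of clusters 2 and 9 were chosen after seeing the data. The causes of the shifts below were not tested unless stated. Genes at least 2-fold higher and lower numbered 12 and 10, and 37 and 18 with no filter on low values and 5 and 5 with a filter at 50 CPM, where the number of genes compared differs by construction. With all retained cells 64 genes were at least 2-fold higher and with the Ncr1 gate 23. Both settings took in cells of the tumour or stroma-like clusters 5 and 8. The Ncr1 gate kept retained cells of any cluster with an Ncr1 UMI and no UMI of Cd3d, Cd3e, Cd3g, Lyz2 or Cd79a. An Ncr1 UMI was found in 62.9% of cells of cluster 5 and 52.3% of cells of cluster 8. With cells matched on UMIs 4 were higher and 3 lower, of which 4 and 2 were among the original genes. For cytotoxic effectors the median of -0.10 was -0.14 with the TMM factor, -0.15 at 50 CPM, -0.20 with all retained cells and -0.18 with the Ncr1 gate. For cytokines and chemokines the median of 0.51 was 0.36 with no filter, 0.42 at 50 CPM, 0.43 with all retained cells, 0.44 with cells weighted equally, 0.36 matched on UMIs, 0.41 without cluster 3 and 0.70 without clusters 2 and 9. With all retained cells the medians were -0.16 for MYC and ribosome biogenesis, -0.22 for glycolysis and -0.12 for amino acid transport and one-carbon metabolism, and with the Ncr1 gate -0.20 and -0.17 for the first and last of these. Matched on UMIs, medians were 0.042 for IL-21 and STAT3 response, -0.19 for MYC and ribosome biogenesis, -0.21 for glycolysis, 0.026 for oxidative phosphorylation, -0.10 for amino acid transport and one-carbon metabolism and 0.28 for the type I interferon response. Of values whose counting bounds excluded 0, these turned sign with the same matching: 0.051 for S phase genes, 0.19 for G2 and M phase genes, and log2 ratios of 0.047 for Clspn, 0.0084 for Fen1, 0.15 for Cdk1, 0.18 for Ccnb1, 0.016 for Mki67, 0.085 for Hmmr, -0.015 for Bbc3, 0.0062 for Klrg1 and -0.077 for Tigit. Of values whose bounds held 0, the median of oxidative phosphorylation turned sign as well, as did Klra1 (-0.0049), Il15ra (-0.15) and Il2ra (0.026), and the medians of Ly49 receptors and of cholesterol and fatty acid synthesis turned under several settings. The median of apoptosis and DNA damage genes was -0.11 at 50 CPM. G2 and M phase genes had a median of -0.037 without clusters 2 and 9. Mature NK genes turned to -0.00078 with the TMM factor, Hmgcs1 to 0.025 with the Ncr1 gate and Klrg1 to 0.016 without cluster 3. Tumour or stroma-like cells made up 4.08% and 8.35% at resolution 1.0, 4.36% and 8.58% with the strict cell filter and 1.79% and 3.92% for cluster 8 alone, and 12.2% of the combination library with doublets kept, so the share was higher in the combination library under each. The planned removal of cycling clusters took cluster 9 alone. Of 113 named genes with a value, 101 kept their sign when cells were matched on UMIs. Depth limits genes near 20 CPM and shares of cells with rare transcripts such as Pdcd1.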

Other observations

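Among lists not described above, immature and memory-like NK genes had a median log2 ratio of 0.25 at percentile 100 and of 0.14 after matching on UMIs per cell, with Cd27 at 126 and 173 CPM and the transcription factor gene Bach2 at 17.0 and 27.3 CPM. The list of TGF-beta and tissue-resident genes had a median of 0.19 at percentile 100 and of 0.03 after matching, with Rgs2 at 296 and 423 CPM. Its members went both ways, with 13 of 19 measured members above 0 and 6 below 0. The median of this list was 0.40 with a filter at 50 CPM and 0.07 with cells weighted equally. Mature NK genes had a median of 0.04 at percentile 82.0, of 0.20 with no filter on low values and of 0.15 both with all retained cells and with the Ncr1 gate, with Klf2, a transcription factor gene, at 537 and 797 CPM and Tbx21, which encodes T-bet, at 200.4 and 243 CPM. Immediate early and heat shock genes had a median of 0.16 at percentile 100 and of 0.05 after matching, above 0 in each of the 7 clusters, with Dusp1 at 378 and 685 CPM and Fos at 150.5 and 226 CPM. Apoptosis and DNA damage genes had a median of 0.04 at percentile 87.3, with Bcl2l11, which encodes BIM, at 140 and 177 CPM. The 7 measured mitochondrially encoded genes had a median of 0.16 at percentile 97.8, and cholesterol and fatty acid synthesis genes a median of -0.0095 at percentile 32.2.

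The MHC class II genes Cd74, H2-Aa and H2-Eb1 were among the leading genes of cluster 3, and within that cluster their log2 ratios were 1.72, 1.46 and 1.14. Outside it they were 0.99, 0.78 and 0.91.

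Of the tests below, those of shared granzyme reads, of the granzymes outside cluster 7, of clusters 2 and 9, of cluster 2 and of UMIs for the interferon list were chosen after the result was seen. For the MYC list, removing cluster 9 alone, by the rule fixed in advance, left the cycling cluster 2 in and tested nothing. Matching on UMIs was itself chosen after seeing the data, with its bounds for the granzyme and MYC tests written before its values were seen.

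The granzyme genes Gzmc, Gzmd, Gzme, Gzmf and Gzmg were lower in the combination library. Reads shared among them would leave their sum alike, and the sum was 1.83-fold higher in the IL-15SA library (1.80 to 1.85). Since each of these genes was lower in the combination library, their sum had to be lower too. The test of the sum therefore decides nothing about shared reads. Matching on UMIs per cell kept 80.6% of the log2 ratio of the sum, above the 75% set in advance. Gzmc makes up most of that sum; singly, Gzmc kept 86.6%, Gzmf 77.3%, Gzmd 73.5%, Gzme 70.0% and Gzmg 57.8%, so part of their difference may go with UMIs per cell. Within cluster 7 the sum was at 6232 CPM in the IL-15SA library and 6496 CPM in the combination library. The ratio of the first over the second was 0.959 (0.932 to 0.987), which met the criterion written in advance for fewer cells of that cluster. These same genes lead that cluster, so the test is void. Outside it the sum was 1.60-fold higher in the IL-15SA library (1.57 to 1.63). The same genes shape that split too. The difference is thus not confined to cells called cluster 7, but this does not test for fewer cells with high levels of these genes. An effect of IL-21Fc and a difference between the mouse pools or libraries cannot be told apart with 1 library per treatment.

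Type I interferon response genes were higher in the combination library. Free RNA of the stroma-like cells, measured from 5 stroma genes at 1.77% and 3.18% of NK compartment UMIs, would account for 7.55% of the summed increase. Without cluster 6, which is led by interferon genes, the list median was 0.35, with the medians of the members' counting bounds at 0.29 and 0.50. The 7.55% argues against free RNA as the whole source. Members of this list lead cluster 6 and so shape that split. The median without it shows only that the increase is not confined to cells called cluster 6. Matching on UMIs per cell kept 66.2% of the list median, so part of the difference may go with UMIs per cell. With 1 library per treatment, a difference between the mouse pools or libraries cannot be told apart from an effect of IL-21Fc.

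MYC and ribosome biogenesis genes were lower in the combination library. Without clusters 2 and 9, the clusters led by cell cycle genes, 93.8% of the list median was kept, so fewer cells of those clusters do not account for it; the S phase median was still -0.32 there, so this does not test cycling in the other cells. Within cluster 2, where the S phase and the G2 and M phase medians were -0.0099 and -0.025, the list median was -0.29. The medians of its members' counting bounds, -0.47 and -0.11, held -0.16, which is 50% of the compartment's value, so neither criterion was met. These are bounds of single genes and not an interval of the list median, so this test cannot decide. The list median was below 0 in each of the 7 clusters. In cluster 4 it was -0.21, where the S phase and the G2 and M phase medians were 0.06 and 0.02. The list was thus also lower where the cell cycle medians were not, but a part played by fewer cycling cells stays open. Matching on UMIs per cell kept 58.7% of the compartment's list median, between the 50% and 75% set in advance. Part of the difference may thus go with the difference in UMIs per cell. Since UMIs per cell also go with cell state, the matching does not decide whether that is technical. With 1 library per treatment, the mouse pools or libraries and IL-21Fc cannot be told apart.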
